A study of Mus musculus with 2 samples.

How the data were processed

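Single-cell RNA sequencing was available for thymic epithelial cells of mice from 1 library labelled Foxp1 KO (Cre+) and 1 library labelled Foxp1 WT (Cre-). Per the labels' protocols, thymi were dissociated mechanically and with liberase and DNase, epithelial cells were enriched on a Percoll gradient, and live EPCAM+ cells were collected by FACS. The genotype field reads KO for both samples, so the title and the library name were used to separate the groups. The number of animals behind each library, their age and sex, the Cre driver and the deleted part of Foxp1 are not given in the sources used here. Whether the reads cover the 3′ or the 5′ end of transcripts, the rule by which barcodes were kept and the use of intronic reads are likewise not given in the sources used here.

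The deposited matrices hold raw UMI counts per gene and barcode, not normalized, made with Cell Ranger 7.0.1 per the file headers. The submitters' processing notes name Cell Ranger, Seurat and the mouse build mm10, without saying which step each served. Both libraries list the same 32285 genes, of which 40 share a symbol with another gene. The lowest total of any barcode is 500 UMIs in both libraries, so a minimum was already in place. Gene positions were taken from the GENCODE annotation release M21 on the same build. Because the matrices give whole-gene counts, UMIs from a gene and from a gene overlapping it on the same strand, and from near-identical copies, could not be separated here. Of the 94 genes named by the ranking below or as focus genes, 6 overlap another annotated gene on the same strand (Cdh8, Sox5, Calm4, Rnase4, Slit2 and Foxp1) and 24 on the opposite strand, so their values are less certain.

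Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were searched for in each library with the scrublet method in scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells (2.87% and 3.23%). It called 0 cells in either library, with highest scores of 0.175 (KO) and 0.237 (WT) under thresholds of 0.276 and 0.266, so doublets were not removed and the caller is taken not to have worked. An alternative chosen after seeing the data left out the cells with the highest scores, 103 and 130, in place of the called ones.

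Both libraries were clustered together without integration: 3000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1. Foxp1, Xist, Y-linked, mitochondrial, ribosomal and haemoglobin genes were kept out of the clustering. The 18 clusters were named from 25 lists of cell type markers fixed before the data were examined. The naming thresholds were set after clusters had been seen, over more than 1 round. A marker counted when it was at least 2-fold above the other cells and present in at least 10% of the cluster's cells. A name needed at least 3 markers and 33% of its list, a mimetic name needed 2 markers among the cluster's 10 leading genes, and an additional name needed 50% of its list. A cluster of low depth without a marker of its class among its leading genes was also left unnamed, which applied to cluster 10. These rules left clusters 3, 4 and 10 unnamed, and their shares are given per library. An earlier exploratory clustering with approximate neighbours divided the Aire-expressing cells differently and was replaced by exact neighbours, so the Aire-stage share depends on the partition. Mimetic cells are medullary epithelial cells that carry the programme of a peripheral cell type. The mimetic class pools tuft-, neuroendocrine-, microfold-, keratinocyte- and ciliated-like clusters. Clusters named for endothelial, fibroblast, mesothelial or thymocyte markers were left out of the epithelial cells.

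With 1 library per group there are no replicates, and no test, p-value or standard error was computed. UMIs were summed over the cells of a class in each library and divided by the class total, scaled to CPM. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95%. These intervals cover counting error only, not variation between animals, dissections, sorts or captures, nor the gathering of a gene's UMIs in single cells. All ratios are given as log2 of the library labelled KO over the library labelled WT. Where a count was 0, the limit given is 3 counts. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs and leaving out shallower cells.

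Differences were summarised over 16 gene lists fixed from general knowledge before the data were examined: Fezf2-linked and Aire-linked self-antigens, maturation regulators of medullary epithelium, mimetic lineage transcription factors, MHC class II presentation, MHC class I presentation, cortical epithelial (cTEC) function, thymic chemokines and co-stimulation, interferon response, keratins, cell cycle, immediate early and heat shock genes, Foxp family, Wnt/Notch/TGF-beta/FGF signalling, cholesterol synthesis and unfolded protein response. Of the 428 entries in the marker and expression lists, 2 were not found among the gene names. Members with at least 20 UMIs over both libraries entered, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test. Genes named outside the lists were ranked by the interval bound nearest to 0, among genes with at least 50 UMIs, a UMI in at least 1% of the cells of the class in the higher library and no cell holding over 20% of that library's UMIs of the gene. The 10 highest and 10 lowest were taken for all epithelial and Aire-stage cells, and the 5 highest and 5 lowest for other classes with at least 100 cells in each library. Mitochondrial, ribosomal, haemoglobin, antigen receptor, Xist and Y-linked genes and gene models without a name were left out of that ranking. For each list, up to 2 members at either end were taken, and other members named were chosen after their values were seen.

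The interval and list computations were tested on simulated counts with 200 genes changed. The counts were independent Poisson draws from the class sums of these libraries, the same error that the intervals assume. Coverage near 95% thus checks the computation only, not real cells, where the UMIs of a gene can gather in few cells. In cluster 3, for example, 1 cell held 19.7% of the Hamp UMIs of the library labelled KO. Over 19007 genes of all epithelial cells the intervals held the true ratio for 95.5% of genes, and changes of 1.5-fold, 2-fold and 4-fold were recovered for 91.0%, 94.0% and 100% of the changed genes. For Aire-stage cells (15367 genes) coverage was 95.6% and recovery 77.6%, 97.0% and 98.5%. For tuft-like cells (10432 genes) coverage was 95.9% and recovery 74.6%, 91.0% and 100%. A planted list of 12 genes stood at percentile 100 in each case, while an unchanged list stood at 79.6, 2.89 and 95.3, so percentiles away from the middle also arise with no difference.

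Alternatives fixed before the data were examined were a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, classes from at least 3 markers per thinned cell, TMM scaling (edgeR 4.0.16 in R 4.3.3), equal weight per cell, thinning to 1000 UMIs or none, other UMI minimums for list members (1 UMI with 0.5 CPM added, or 100 UMIs) and 200 UMIs for named genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. 1 gene-level result is not reported here.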

Results

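The data collected were droplet single-cell transcriptomes of sorted EPCAM+ thymic epithelial cells from mice, 1 library labelled Foxp1 KO (Cre+) and 1 labelled Foxp1 WT (Cre-). Foxp1 is a forkhead transcription factor, and the series concerns its part in gene expression that depends on Fezf2, in the diversity of mimetic medullary thymic epithelial cells (mTECs) and in tolerance. Medullary cells display proteins of peripheral tissues to developing T cells, a programme to which the regulators Aire and Fezf2 contribute, and mimetic mTECs take on features of peripheral cell types such as tuft cells or keratinocytes. The library labelled KO held 4277 barcodes with 25233944 UMIs and the library labelled WT 4957 barcodes with 33120715 UMIs. After filtering, 3584 (83.8%) and 4037 (81.4%) cells remained, with medians of 5097.5 and 6267 UMIs and of 2225 and 2519 genes per cell. Of these, 3267 and 3883 cells were in epithelial clusters. Since each group is 1 library, none of the differences has a replicate check.

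Foxp1 (ENSMUSG00000030067, chromosome 6, 98925338 to 99522721, minus strand, mm10) was higher in the library labelled KO. Over all epithelial cells its level was 405 CPM (95% interval 396 to 413, counting error only) in the library labelled KO and 252 CPM (247 to 258) in the library labelled WT, a log2 ratio of 0.68 [0.64, 0.73]. The ratio was above 0 in 13 of the 14 epithelial clusters. Of the classes compared it was highest in neuroendocrine-like cells, at 1212 against 563 CPM (1.10 [1.0, 1.21]), and lay at 0.73 in keratinocyte- and basal-like cells, 0.62 in cycling cells, 0.50 in Aire-stage cells, 0.41 in tuft-like cells and 0.25 in Ccl21-expressing mTEC-like cells, where the 3 pooled clusters had 0.18 (cluster 0), 0.53 (cluster 8) and 0.39 (cluster 9), so the pooled value also reflects their different mixture in the 2 libraries. At 2000 UMIs per cell, 45.7% and 36.4% of epithelial cells had a Foxp1 UMI (0.33 [0.22, 0.44]). In Aire-stage cells the ratio of these shares was 0.73 [0.27, 1.20] at 2000 UMIs but 0.11 [-0.54, 0.76] at 1000 UMIs. In Ccl21 mTEC-like and tuft-like cells it was 0.11 [-0.07, 0.29] and 0.28 [-0.02, 0.57] at 2000 UMIs, and 0.36 [0.16, 0.57] and 0.47 [0.10, 0.84] at 1000 UMIs. In cluster 3, an unnamed mTEC cluster described below, both libraries had similar Foxp1 levels (153 and 154 CPM). Of its relatives, Foxp4 was lower in the library labelled KO (107 against 135 CPM, -0.33) and Foxp2 was similar (13.4 and 13.2 CPM). The Foxp family list thus had 3 measured members and a median of 0.02 (percentile 60.2). The whole-gene count of Foxp1 goes against the label. It cannot show a deletion that leaves the counted part of the transcript in place, and the gene Gm20705 overlaps Foxp1 on the same strand. The groups are therefore called the library labelled KO and the library labelled WT, and every direction given here rests on those labels.

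To compare the makeup of the epithelium, cells were grouped by their marker genes. Ccl21-expressing mTEC-like cells, which make a chemokine that draws T cells into the medulla, took 31.9% [30.3, 33.5] of epithelial cells in the library labelled KO and 24.4% [23.1, 25.8] in that labelled WT, a log2 ratio of 0.39 [0.26, 0.51]. The class pools clusters 0, 8 and 9, in which 94.2%, 95.1% and 93.9% of cells had a Ccl21a UMI. The Ccl21a level was 15662 CPM in cluster 0 but 2530 and 2941 CPM in clusters 8 and 9, beside 1897 CPM in cycling cells. Ccl21a led only cluster 0, beside the pericyte markers Tagln and Acta2, and pericyte markers were the next best list for all 3 clusters. The difference in share came from cluster 0 (12.9% and 6.98%, 0.89 [0.66, 1.11]) and cluster 9 (8.17% and 5.36%, 0.61 [0.34, 0.88]), while cluster 8 went the other way (10.8% and 12.1%, -0.16 [-0.36, 0.04]). Aire-stage cells took 13.4% [12.3, 14.6] and 17.6% [16.5, 18.9] (-0.40 [-0.57, -0.22]), and mimetic cells together 23.3% and 28.8% (-0.30 [-0.44, -0.17]). Among mimetic cells, tuft-like cells, which resemble chemosensory cells of mucosae, were fewer, at 265 cells (8.11% [7.20, 9.10]) against 503 cells (13.0% [11.9, 14.1]), a ratio of -0.68 [-0.90, -0.46]. Keratinocyte- and basal-like cells took 6.18% and 8.14% (-0.40 [-0.66, -0.14]). Neuroendocrine-like cells took 5.36% and 4.2% (0.35 [0.04, 0.67]), ciliated-like cells 1.29% and 0.747% (0.78 [0.07, 1.52], from 42 and 29 cells), and a cluster with microfold and enterocyte markers 2.39% and 2.76% (-0.21 [-0.65, 0.23]), a difference not detectable at this depth, though the ratio was -0.37 [-0.71, -0.03] without the highest doublet scores. Cycling cells took 9.86% and 8.34% (0.24 [0.01, 0.47]).

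Cluster 3, led by Nos2, Prap1, Fabp9, Lypd8 and Saa3, stayed unnamed and took 10.1% and 12.03% (-0.26 [-0.46, -0.05]). Clusters 4 and 10 held cells of low RNA content (medians of 1992.5 and 1765 UMIs) and took 2.45% and 9.0% of the library labelled KO against 5.51% and 3.27% of the library labelled WT. The best list of cluster 10 was that of Ccl21 mTECs (4 of 7 markers), and 85.0% of its cells had a Ccl21a UMI. It was left unnamed for its low depth, so the Ccl21 share also depends on that rule. At the resolution used, no cluster was named for cortical epithelium. At resolution 2 a cluster led by Prss16, Psmb11, Ctsl and Ccl25 held 30 cells of the library labelled KO and 1 of that labelled WT, so such cells were present but not separated. With classes from markers per cell the excess was not seen, at 60 of 2777 and 88 of 3454 cTEC-like cells (-0.24 [-0.74, 0.25]). That rule can also take in Aire-stage cells, for which the cTEC markers were the next best list, so it does not count this cluster alone. Clustered on its own, the library labelled KO had a cTEC-like cluster of 31 cells, and the library labelled WT had no such cluster. The shares are of sorted EPCAM+ cells, and epithelial cells of the library labelled KO were shallower (median 5218 against 6351 UMIs). Clustered on their own, the libraries had Aire-stage shares of 16.5% and 16.2% (0.02), which turns the direction given above, cycling shares of 5.90% and 1.93% (1.61), a keratinocyte- and basal-like ratio of -0.72 and a Ccl21 ratio of 0.57. The Ccl21 ratio was also 0.58 both at resolution 0.5 and without the highest doublet scores, the cycling ratio was 0.63 with classes from markers per cell, and the interval of the cycling ratio included 0 without the highest doublet scores (0.02 [-0.24, 0.29]), under the stricter filter (0.11), at resolution 0.5 (0.13) and at resolution 2 (0.31 [-0.12, 0.75]). The Aire-stage shares at resolution 2 were 5.52% and 6.65% (-0.27 [-0.55, 0.01]), an interval that also includes 0. The neuroendocrine-like class gave no ratio under 3 of the alternatives, for want of a named cluster, and a ratio of 0.25 [-0.05, 0.54] with classes from markers per cell.

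**Figure D1:**
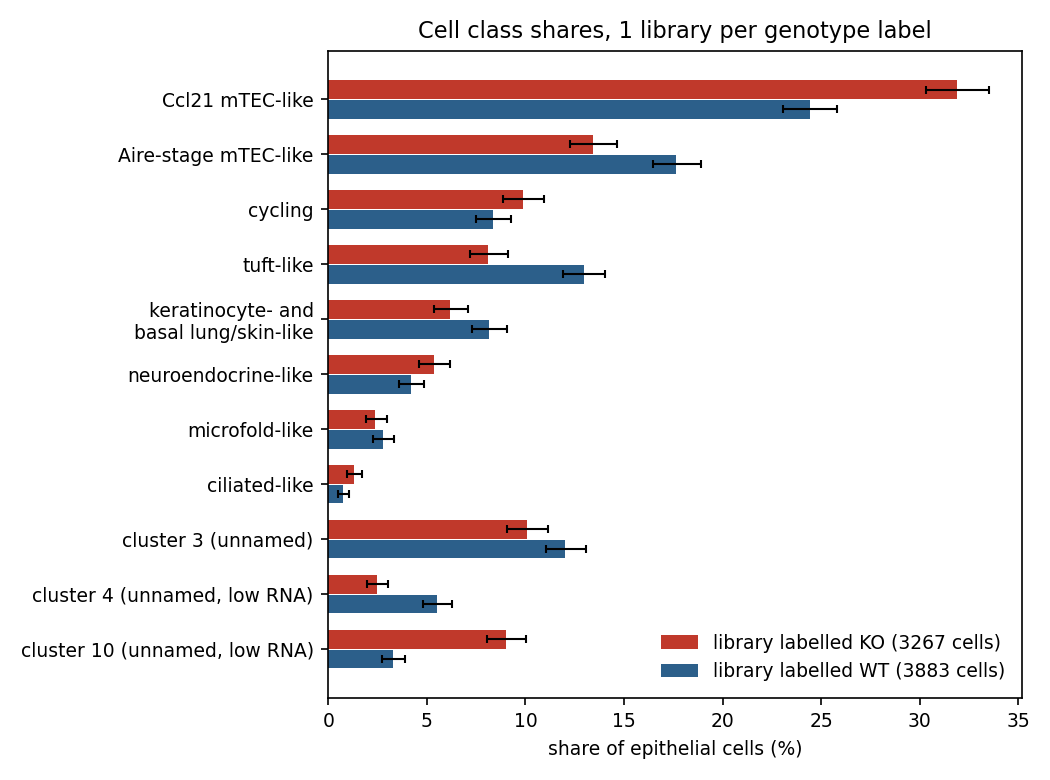
Share of epithelial cells (percent, x axis) in each class and in the unnamed clusters 3, 4 and 10 for the library labelled KO and the library labelled WT; bars start at 0 and error bars are Clopper-Pearson 95% intervals (counting error only). Tuft-like cells stand at 8.11% and 13.0%, Aire-stage cells at 13.4% and 17.6%, and Ccl21 mTEC-like cells at 31.9% and 24.4%.

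Fezf2, a zinc finger factor needed for part of the self-antigens of mTECs (ENSMUSG00000021743, chromosome 14, 12342094 to 12348189, minus strand), was lower in the library labelled KO in Aire-stage, cycling and cluster 3 cells. In Aire-stage cells it stood at 420 CPM [403, 439] against 531 CPM [516, 547], a log2 ratio of -0.34 [-0.41, -0.26]. In cycling cells it stood at 357 against 534 CPM (-0.58 [-0.68, -0.48]), in cluster 3 at 266 against 333 CPM (-0.32 [-0.46, -0.19]) and over all epithelial cells at 240 against 327 CPM (-0.45 [-0.50, -0.40]). In Ccl21 mTEC-like cells the levels were 84.4 and 90.1 CPM (-0.09 [-0.31, 0.12]), and in the low-RNA cluster 4, where Fezf2 was also abundant, 406 and 480 CPM (-0.24 [-0.57, 0.09]). The share of Aire-stage cells with a Fezf2 UMI at 2000 UMIs per cell was 43.6% [38.9, 48.4] (190 of 436) against 54.9% [51.1, 58.7] (374 of 681), with 2 and 4 shallower cells left out. Without thinning it was 77.9% and 86.3%. At 2000 UMIs the shares were 43.2% and 54.8% in cycling cells and 31.1% and 38.4% in cluster 3, where the interval of the ratio included 0 (-0.31 [-0.68, 0.07]). At 1000 UMIs cluster 3 had 21.3% and 20.1% (0.08 [-0.39, 0.54]), so its lower level is not borne out by detection at that depth. Fibroblast-like cells, which should lack Fezf2, had 0 of 22 and 0 of 12 cells with a UMI, which allows shares of up to 13.6% and 25%, at median depths of 3978 and 4351 UMIs against 10336.5 and 11581 UMIs in the Aire-stage cells. Without thinning, however, 85 of 254 and 42 of 96 endothelial-like cells (282 and 298 CPM) and 6 of 29 and 9 of 39 thymocyte-like cells had a Fezf2 UMI, and Aire was likewise found in 90 and 44 of these endothelial-like cells, so RNA of both genes also occurs in droplets of other cell types.

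Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610, minus strand) has a product that opens expression of many tissue-restricted genes. Like Fezf2, it was lower in cycling cells and cluster 3 of the library labelled KO, but not in Aire-stage cells. Within Aire-stage cells it was slightly higher in the library labelled KO, at 971 against 878 CPM (0.14 [0.09, 0.20]), and the share of cells with an Aire UMI at equal depth was 73.4% and 74.4% (94.98% and 94.89% without thinning). Of fibroblast-like cells 0 of 22 and 0 of 12 had an Aire UMI at equal depth, and 1 of 24 and 0 of 12 without thinning. Aire was lower in the library labelled KO in cycling cells (475 against 608 CPM, -0.36), in cluster 3 (316 against 417 CPM, -0.40), in neuroendocrine-like cells (65.2 against 162 CPM, -1.31), in tuft-like cells (-0.59 [-0.90, -0.30]) and over all epithelial cells (359 against 426 CPM, -0.25 [-0.29, -0.21]). From lower levels, it was higher in cluster 0 (1.99 [0.81, 3.40], 39 and 7 UMIs), ciliated-like cells (1.27 [0.24, 2.44]) and microfold-like cells (0.83 [0.18, 1.49]). Fezf2 and Aire are among the 9 markers used to name the Aire-stage cluster and were not kept out of the clustering. The similar Aire of both libraries in that cluster is thus partly set by how its cells were grouped. Equal weight per cell gave an Aire ratio of -0.38 over all epithelial cells, more than 1.5 times as far from 0.

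**Figure D2:**
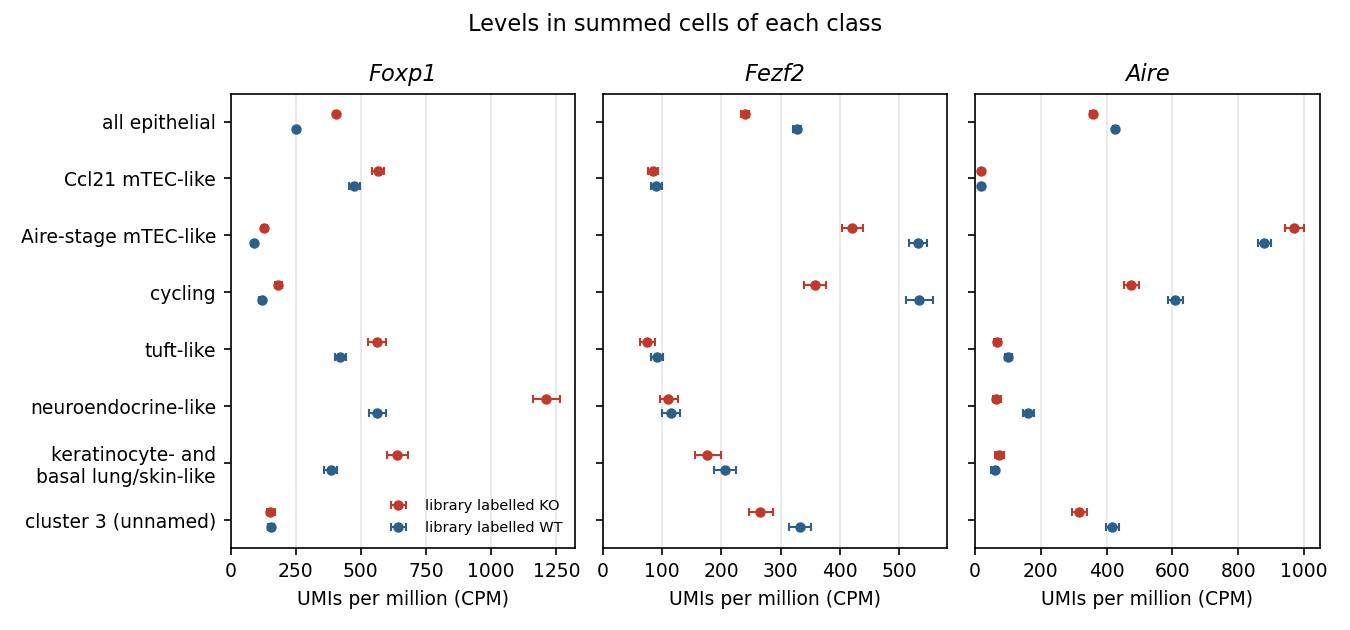
Foxp1, Fezf2 and Aire levels (CPM of summed UMIs, x axis) by cell class in the library labelled KO and the library labelled WT, with exact Poisson 95% intervals (counting error only). Foxp1 is higher in the library labelled KO in neuroendocrine-like cells (1212 and 563 CPM), and Fezf2 is lower in it in Aire-stage cells (420 and 531 CPM) and cycling cells (357 and 534 CPM).

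The self-antigen lists in Aire-stage cells were then compared, since the series names Fezf2-dependent expression. Of 11 measured Fezf2-linked genes, 7 were higher and 4 lower in the library labelled KO. The lowest were Fabp9, a fatty acid binding protein of testis (13.3 against 54.6 CPM, -2.04), the keratin Krt10 (-0.56) and the apolipoprotein Apoc3 (-0.52). Fabp9 is also a leading gene of clusters 3 and 4, so its ratio in Aire-stage cells may depend on how cells were grouped. The highest were the calcium-binding protein Calb1 (40.6 against 20.3 CPM, 1.0) and the thyroid hormone carrier Ttr (0.77). The median was 0.22 (percentile 99.2) and the mean -0.02, of opposite sign, and the median was 0.08 without the highest doublet scores and 0.09 with equal weight per cell. Of 14 Aire-linked genes, 6 were higher and 8 lower, with a median of -0.13 (percentile 8.61). The lowest were the urinary protein Mup4 (-1.33) and the insulin gene Ins2 (66.1 against 129 CPM, -0.96), and the highest was Obp1a, an odorant-binding protein, at 2.57. S100a8 and Pcp4 of that list also lead the Aire-stage cluster and are not read as differences. Mup4 and Obp1a belong to multigene families whose UMIs may be split between copies, so their values are uncertain.

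Heat shock genes lay almost all on the same side in these cells. Of 16 immediate early and heat shock genes, which respond to tissue dissociation, 15 were lower in the library labelled KO, with a median of -0.35 (percentile 0). The inducible chaperone genes Hspa1b (143 against 366 CPM, -1.35) and Hspa1a (146 against 329 CPM, -1.17), near-identical copies whose UMIs cannot be fully separated, were the lowest. The unfolded protein response list was lower for 9 of 11 genes (-0.12, percentile 9.12), led by the factor Xbp1 (-0.56). By contrast, 11 of 14 interferon response genes were higher, with a median of 0.24 (percentile 100), among them the antiviral genes Ifit3 (30.7 against 14.7 CPM, 1.07) and Rsad2 (1.03) and the ubiquitin-like modifier Isg15 (0.55). Of 17 maturation regulators, 13 were lower (-0.13, percentile 4.27), among them the interferon regulatory factors Irf8 (144 against 210 CPM, -0.54) and Irf4 (-0.47), while Prdm1 was higher (0.53). Of 12 cTEC function genes, 8 were lower (-0.28, percentile 0.46; -0.51 with equal weight per cell), including the chemokine Ccl25 (155 against 435 CPM, -1.49 [-1.60, -1.38]), Cd83 (-1.20) and Foxn1, the master regulator of thymic epithelium (50.02 against 109.5 CPM, -1.13).

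The other lists in Aire-stage cells had medians between -0.17 and 0.27. Mimetic lineage transcription factors were lower for 13 of 20 (-0.17), with Neurod1 at 0 UMIs in the library labelled KO and the pioneer factor Foxa2 at 2.07. Keratins were lower for 8 of 15 (-0.16), MHC class I genes for 6 of 11 (-0.06) and cholesterol synthesis genes for 7 of 12 (-0.06). MHC class II genes were higher for 7 of 11 (0.02), chemokine and co-stimulation genes for 8 of 16 (0.06), with the chemokines Xcl1 (71.3 against 18.3 CPM, 1.96) and Ccl17 (0.87) the highest, signalling genes for 13 of 20 (0.11), with Lgr5 at 2.39, and cell cycle genes for 10 of 16 (0.24), with Ccnb1 (1.90) and Cenpf (1.72) the highest. The Foxp family median was 0.27. Outside the lists, the genes most clearly higher in the library labelled KO were Mgp, a matrix inhibitor of calcification (65.5 against 15.4 CPM, 2.08), the factor Sox5 (1.94), Tnni3k, Uts2b, Ly6m, the collagen gene Col3a1 (11.4 against 3.16 CPM, 1.86), Egfem1, Pga5, Kif2c and Tenm1. Mgp is also a leading gene of Ccl21 cluster 0 and Col3a1 of the fibroblast-like cluster. They had a UMI in only 9.36% and 2.74% of Aire-stage cells of the library labelled KO. Doublets or stray RNA may thus account for these 2 ratios, which was not tested. The most clearly lower, with the list members Fabp9 and Ccl25 among them, were the gasdermin Gsdmc2 (5.63 against 33.8 CPM, -2.59), Fxyd7, Aunip (114 against 407 CPM, -1.84), the tachykinin precursor Tac1 (-2.03), Fabp9, Meg3, the pancreatic colipase Clps (18.7 against 68.6 CPM, -1.88), Calm4, Ccl25 and Pmp2. Of these, Calm4 is also a leading gene of keratinocyte- and basal-like cluster 1, and Fabp9 of clusters 3 and 4.

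**Figure D3:**
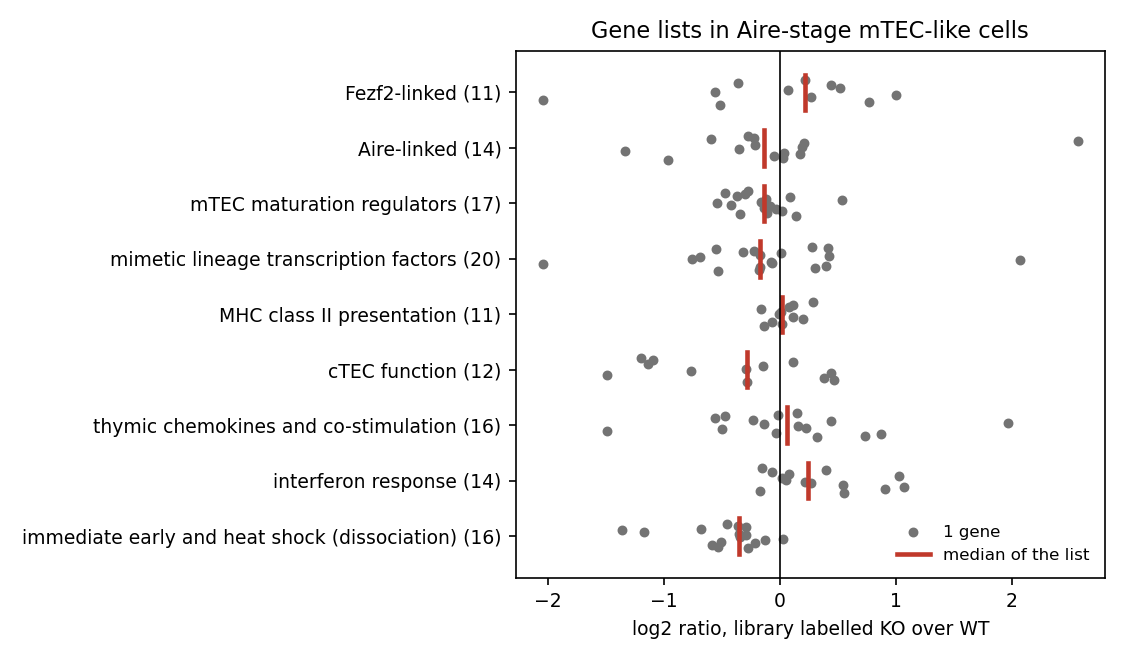
Log2 ratio of CPM, library labelled KO over library labelled WT, of each member of 9 gene lists in Aire-stage mTEC-like cells, 1 point per gene with the list median; Neurod1, with 0 UMIs in the library labelled KO, is not drawn. The heat shock list lies mostly below 0 (median -0.35) and the interferon list mostly above 0 (median 0.24).

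Over all epithelial cells, the levels combine differences within classes with the different shares of classes. Of 14 Aire-linked genes, 11 were lower in the library labelled KO (median -0.32, percentile 0), among them Mup4 (-1.10) and the zona pellucida gene Zp3 (-0.75), whereas the 12 Fezf2-linked genes divided 6 to 6 (0.03, percentile 75.9), from Fabp9 at -0.51 to Ttr at 0.84. Of 17 maturation regulators, 16 were lower (-0.12, percentile 1.66), the lowest being the deacetylase Sirt1 (205 against 296 CPM, -0.53), and all 11 unfolded protein response genes were lower (-0.18, percentile 0.90), the lowest being Xbp1 (-0.37) and the chaperone Hspa5 (-0.36). Immediate early and heat shock genes were lower for 11 of 16 (-0.08, percentile 7.34). Cell cycle genes were higher for 14 of 16 (0.26, percentile 99.96), with Cenpf and Ccnb1 both at 0.77, and interferon genes for 10 of 14 (0.18, percentile 99.95). Wnt, Notch, TGF-beta and FGF genes were higher for 15 of 21 (0.09, percentile 97.5), with the Notch target Hey1 (17.1 against 6.93 CPM, 1.30) the highest.

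The other lists over all epithelial cells had medians between -0.12 and 0.04. Mimetic transcription factors were lower for 14 of 20 (median -0.11, mean 0.02), with the tuft regulator Pou2f3 at -0.54 and Trp73, a p53 relative of ciliated cells, at 1.05. MHC class II genes were lower for 8 of 11 (-0.12), MHC class I genes for 6 of 11 (-0.03) and keratins for 9 of 15 (-0.10). cTEC function genes divided 6 to 6 (0.01), with Prss16, a protease of cortical epithelium, at 1.68 and Foxn1 at -0.89. Chemokine and co-stimulation genes were higher for 9 of 16 (0.04), with Xcl1 at 1.42 and Ccl25 at -0.78, and cholesterol synthesis genes for 7 of 12 (0.04). The genes most clearly higher outside the lists were the engulfment receptor Megf10 (3.12 against 0.358 CPM, 3.13 [2.2, 4.19]), Xlr3b, the caveolar protein Cavin2, Mfap2, the adenylyl cyclase Adcy4, Igll1, Cdkl1, the claudin Cldn8 and Cyp2d22. The most clearly lower were the mast cell protease Mcpt2 (3.17 against 18.2 CPM, -2.52 [-2.90, -2.17]), Gsdmc2, Clps, Aunip (68.7 against 249 CPM, -1.86), Zfp382, the cadherin Cdh8, Retnla, Rnase2a, Ripply2 and Dppa5a. Several of these are low in both libraries, and Xlr3b and Gsdmc2 have close copies.

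In Ccl21 mTEC-like cells, all 11 measured cTEC function genes had ratios above 0 (median 0.95, percentile 100), 9 of them with an interval above 0. Kitl (0.01 [-0.30, 0.33]) and Foxn1 (0.04 [-0.28, 0.36]) were level. Prss16 stood at 150 against 12.4 CPM (3.60), the thymoproteasome subunit Psmb11 at 25.2 against 2.68 CPM (3.23), Cd83 at 2.99 and Ccl25 at 2.37. Much of this came from the 30 and 1 cells that form the cTEC-like cluster at resolution 2. Without them the median of the 10 genes still measured was 0.32, with 8 higher and 2 lower, a comparison chosen after seeing the data. Prss16 then stood at 1.15 [0.66, 1.65], Psmb11 at 0.98 [-0.43, 2.53] and Ccl25 at 0.02 [-0.41, 0.46]. Of the 8 higher genes, only Prss16, Il7, Ctsl and Tbata had an interval above 0. Cholesterol synthesis genes were higher for 9 of 12 (0.44, percentile 99.9), among them the isomerase Idi1 (1.20) and the sterol sensor Insig1 (1.09). Interferon genes had ratios below 0 for 14 of 14 (-0.23, percentile 1.20), 8 of them with an interval below 0. In Aire-stage cells 11 of 14 had ratios above 0, 7 of them with an interval above 0. The largest cluster of this class was cluster 0 in the library labelled KO (422 of 1042 cells) and cluster 8 in that labelled WT (469 of 948), so the values compare unlike mixtures. Outside the lists, Aox3 (28.8 against 2.19 CPM, 3.72) and Crip3 (3.08) were the most clearly higher and Cyyr1 (25.4 against 184 CPM, -2.86), Kcnip4, Alpk2, Matn1 and the interleukin receptor gene Il2ra (-1.69) the most clearly lower. Crip3 had a UMI in 4.61% of these cells in the library labelled KO. It is also a leading gene of the cTEC-like cluster seen when that library was clustered on its own.

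Tuft-like cells, besides being fewer in the library labelled KO, had lower levels of antigen presentation genes there. Of 11 MHC class II genes, 10 were lower (median -0.46, percentile 0), among them the transactivator Ciita (19.6 against 37.9 CPM, -0.95) and H2-Aa (517 against 769 CPM, -0.57), while the protease Ctsl was higher (0.83). Of 11 MHC class I genes, 10 were lower (-0.19, percentile 1.66). Without the highest doublet scores the class II median was -0.19. Maturation regulators were lower for 15 of 17 (-0.28), and Aire-linked genes for 8 of 10 (-1.21; -0.39 without the highest doublet scores). Myog, a muscle regulator (227 against 68.0 CPM, 1.74), and Hes6 (291 against 95.6 CPM, 1.61) were higher, as were Adcy4 (2.88), the necroptosis kinase Ripk3 (2.78) and Kcnk1. Cluster 12, which Myog helps to lead, held 58 of the 265 and 78 of the 503 tuft-like cells, so these values too compare unlike mixtures. Prap1, the microfold gene Gp2 (30.2 against 142 CPM, -2.23), Lypd8, Hspa1b and Skint7 were lower. Pou2f3, which tuft cells require, stood at -0.23, and the median of the 12 tuft markers was -0.11.

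Over all mimetic cells, lineage transcription factors were higher for 14 of 19 measured genes (median 0.19, percentile 99.1), with Trp73 (2.01), the pancreatic factor Ptf1a (1.28) and Myog (1.25) the highest and Grhl3, a factor of keratinocyte differentiation, the lowest (12.2 against 23.0 CPM, -0.91). These pooled cells are unlike mixtures, with 265 tuft-like, 175 neuroendocrine-like and 42 ciliated-like cells among 762 in the library labelled KO and 503, 163 and 29 among 1118 in that labelled WT, so the ratios also reflect these proportions. In neuroendocrine-like cells, the genes most clearly higher in the library labelled KO included the glutamate receptor gene Grin2b (131 against 30.1 CPM, 2.12), the synaptic adhesion gene Nrxn3 (500 against 173 CPM, 1.53), St8sia1 and Galnt13. Dclk1 (86.0 against 431 CPM, -2.33), Nrgn, Slit2, Hspa1a and Hspa1b were lower. Of these, Dclk1 and Nrgn are also leading genes of tuft cluster 2, and Slit2 of tuft cluster 12. The 10 neuroendocrine markers divided 5 to 5 (median -0.02, from -2.00 to 1.23). The values of this class, its Foxp1 ratio among them, may therefore compare unlike cells. In keratinocyte- and basal-like cells, Chst9, the uroplakin Upk1b (90.0 against 15.5 CPM, 2.54), Agmo, Rarres1 and Pdpn were higher, and the stefin Stfa3, Mctp1, Fam25c (193 against 555 CPM, -1.53), the endothelin Edn1 and Klf2 were lower. Of the 18 markers of this class 14 were lower in the library labelled KO (median -0.26).

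Other cell types and signs of RNA quality were also compared between the libraries, with markers of other types summed over all epithelial cells and not per class. Despite the EPCAM sort, endothelial-like cells made up 7.09% [6.27, 7.98] of kept cells in the library labelled KO and 2.38% [1.93, 2.90] in that labelled WT (254 and 96 cells), and all non-epithelial clusters together 8.84% and 3.81%. Thymocyte-like cells took 0.809% and 0.966%, fibroblast-like cells 0.670% and 0.297% and mesothelial-like cells 0.279% and 0.173%. Within epithelial cells, summed markers of other types had log2 ratios of 0.56 for mesothelial, 0.21 for endothelial, 0.20 for myeloid, 0.13 for fibroblast, 0.09 for thyroid, -0.02 for pericyte, -0.18 for thymocyte, -0.20 for B cell and -0.29 for erythroid cells. Parathyroid markers stood at -2.15, where 1 cell of the library labelled WT held 2259 of its 3060 Pth UMIs. Barcodes over the mitochondrial limit made up 12.8% and 15.1%, and the median mitochondrial share of kept cells was 2.49% and 2.41%. Epcam itself was higher in the library labelled KO over all epithelial cells (619 against 546 CPM, 0.18).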

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

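Leaving out the cells with the highest doublet scores, the low-RNA clusters 4 and 10 or the cTEC-like cells were alternatives chosen only after the data were seen; the others were fixed before the data were examined. No paired analysis was possible because each group is 1 library. Keeping doublets gave the same cells, since no doublet had been called. Foxp1 stayed above 0 in all epithelial cells, and the tuft-like share lay between -0.48 (stricter cell filter) and -0.69 (highest doublet scores left out, and markers per cell). Among recomputed shares, 56 stayed inside the 95% interval of the value given above, 7 lay outside it and 1 changed sign. With each library clustered on its own, the Aire-stage ratio turned to 0.020, the cycling ratio was 1.61, the keratinocyte- and basal-like ratio -0.72 and the Ccl21 ratio 0.57. At resolution 0.5 the Ccl21 ratio was 0.58 and that of all mimetic cells -0.45. The Ccl21 ratio was 0.58 without the highest doublet scores, and the cycling ratio 0.63 with classes from markers per cell, while the counting interval of the cycling ratio included 0 under 4 alternatives, that of the Aire-stage ratio at resolution 2 and that of the neuroendocrine-like ratio with markers per cell, and that of the microfold-like ratio excluded 0 without the highest doublet scores. At resolution 0.5 the mimetic class held no neuroendocrine-like cluster, a class whose ratio was 0.35 at the resolution used. Beyond that, the cause was not tested for these moves. Equal weight per cell gave Fezf2 ratios of -0.43 in Aire-stage and -0.52 in all epithelial cells and an Aire ratio of -0.38 in all epithelial cells; deep cells then count no more than shallow ones, and beyond that the cause was not tested. The neuroendocrine-like class gave no ratio at resolution 0.5 or under the stricter filter, where no cluster of the 2 libraries together took that name. It gave none with separate clustering either, where at least 1 library had no cluster of that name. Among recomputed single genes 470 stayed inside their intervals and 45 did not, and among list medians 677 did and 6 did not. Some list medians near 0 changed sign, as for the cell cycle list over mimetic cells, at -0.13 and at 0.12 without the highest doublet scores. The genes picked by the ranking were less stable: 29 recomputed sets kept most of the genes, 17 shared so few with the original set that its size was over 1.5 times the overlap, and with equal weight per cell 12 of 20 genes over all epithelial cells and 10 of 20 in Aire-stage cells were picked again. TMM scaling moved no gene, list median or picked set in this sense. The depth of small classes limits what can be seen, as for the 42 and 29 ciliated-like cells, and list members under 20 UMIs in a class were not read.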

Other observations

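Some heat shock genes were lower in the library labelled KO in each of the 7 classes compared, beyond the Aire-stage cells: Hspa1a from -1.94 to -0.71, Hspa1b from -2.08 to -0.83, the co-chaperone Dnajb1 from -1.32 to -0.31 and the constitutive chaperone Hspa8 from -0.77 to -0.36. The whole immediate early and heat shock list did not go this way in cycling cells (8 higher and 8 lower, median 0.02) or tuft-like cells (9 higher and 7 lower, 0.03). The lysosomal protease Ctsl was higher in 7 of 7 classes (0.11 to 0.95), and Foxn1 was lower in 6 of 7, the exception being Ccl21 mTEC-like cells (0.04 [-0.28, 0.36], and -0.11 [-0.44, 0.22] without the cTEC-like cells). These genes were chosen after their values were seen. Cycling cells had 10 of 14 interferon genes higher (median 0.48, percentile 100), led by Isg15 (163 against 79.2 CPM, 1.04), 11 of 12 cholesterol synthesis genes higher (0.33, percentile 99.96) and 7 of 9 Fezf2-linked genes higher (0.46), although Fezf2 itself was lower there. In cluster 3, where 9 of 12 cTEC function genes were lower (-0.70, or -0.28 with equal weight per cell), the iron regulator Hamp stood at 1777 against 567 CPM (1.65), the growth factor Areg at 2.79 and the chemokine Ccl5 at 682 against 1888 CPM (-1.47).

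With classes from markers per thinned cell, the rarer mimetic lists gave 11 and 8 muscle-like, 21 and 24 goblet-like and 3 and 2 pancreatic-like cells of 2777 and 3454, and ionocyte-like cells were 1 against 9, a log2 ratio of -2.86 [-8.31, -0.0038]. At resolution 2 an enterocyte- and hepatocyte-like class, not separate at resolution 1, held 67 and 113 cells (-0.50 [-0.96, -0.06]). Endothelial-like cells with an Epcam UMI, 112 and 46, had median depths of 10126.5 and 14899 UMIs, whereas the 142 and 50 without had 2410.5 and 3209.5. Adcy4 and Ripk3, both higher in tuft-like cells of the library labelled KO, are neighbours on chromosome 14, 899 bases apart (55769057 to 55784095 and 55784995 to 55788865), and Mcpt2, among the lowest genes over all epithelial cells, begins 253175 bases beyond Ripk3.

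For the following 3 patterns, the tests of the mitochondrial limit, of Aire levels and of the heat shock response were set down before their results were seen, and the tests of cluster mixture, free Foxp1 RNA, exchanged labels, depth, the denominator and free Fezf2 RNA were chosen only after.

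Foxp1 was higher, not lower, in the library labelled KO. A different mixture of clusters is argued against, since with clusters weighted as in the library labelled WT the log2 ratio was 0.57 [0.52, 0.61] (0.68 unweighted). Free Foxp1 RNA in the droplets is argued against as the whole of the difference by an excess of 648 CPM [586, 709] in neuroendocrine-like cells against -1.12 CPM [-20.5, 18.6] in cluster 3, of similar depth. Neuroendocrine-like cells of the 2 libraries may be unlike cells, as said above, so the size of their excess is uncertain and a part from free RNA stays open. Libraries with exchanged labels cannot be told apart from a true label, because 0 genes of the matrices are named for the Cre recombinase and whole-gene counts do not show a deleted part. A transcript that keeps its counted end, or feedback of a lost protein on its own gene, may also give this pattern and was not tested, nor was a difference between animals or preparations.

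The smaller share of tuft-like cells in the library labelled KO may reflect its genotype, as a hypothesis, or the animal, dissection or sort behind that library, which this design leaves open. Loss of tuft-like cells to the mitochondrial limit was tested only among barcodes with at least 500 genes and 2000 UMIs, of any mitochondrial share. Their log2 ratio of cells with tuft markers was -0.67 [-0.88, -0.46] (275 of 2865 against 546 of 3575). Most of these barcodes were kept cells (2777 and 3454), whereas 549 and 749 barcodes lay over the limit. The test thus reached few of the barcodes over the limit and cannot decide, so such a loss stays open. Lower depth is argued against by -0.69 [-0.91, -0.47] among kept cells at 2000 UMIs (253 of 2777 against 507 of 3454). More Ccl21 mTEC-like and low-RNA cells in the denominator took part of the difference but left -0.44 [-0.66, -0.22] among the remaining epithelial cells.

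Fezf2 was lower in Aire-stage, cycling and cluster 3 cells of the library labelled KO, together at -0.41. In cluster 3 the share of cells with a UMI did not bear this out at 1000 UMIs (0.08 [-0.39, 0.54]). With cells matched on thinned Aire UMIs (0, 1, 2, 3 or more), the log2 ratio was -0.38 [-0.43, -0.32]. Matched in the same way on Hspa1a and Hspa1b UMIs, it was -0.49 [-0.56, -0.43]. So few UMIs per thinned cell sort cells only coarsely by Aire level or heat shock response. These ratios therefore cannot decide whether a different mixture of Aire levels or the weaker heat shock response plays a part, and both stay open. Free Fezf2 RNA in the library labelled WT is argued against as the whole of the difference, since the difference was -66.7 CPM [-93.9, -39.7] in cluster 3, where it was smallest, and -111 CPM [-135, -87.4] in Aire-stage cells, but -4.0 CPM [-25.6, 17.6] in neuroendocrine-like cells. Fezf2 was also lower in thymocyte-like cells (116 against 210 CPM, -0.85 [-1.70, -0.07], from 18 and 58 UMIs), keratinocyte- and basal-like cells (-0.23), cluster 9 (-0.45) and cluster 12 (-0.58). In endothelial-like cells it was similar (-0.08 [-0.29, 0.14]). In microfold-like (0.34 [-0.21, 0.89]) and ciliated-like cells (0.31 [-0.31, 0.95]) the ratio lay above 0 with an interval that included 0. Fezf2 UMIs in endothelial- and thymocyte-like droplets show that mixed or stray RNA does occur, so a part from free RNA stays open. A dependence of Fezf2 on Foxp1 is a hypothesis that would be in line with these values only if the labels hold, and animal, preparation and capture differences stay open.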
